A study of Mus musculus with 6 samples.

How the data were processed

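The series holds 6 liver libraries from male C57BL/6J mice, 2 weeks old at the start per the labels, in 2 groups given by the labels: 3 control and 3 DEN+CCl4. Per the labels' protocols, poly(A) RNA was purified from 5 ug of total RNA with a RIN above 7 and made into libraries with a SMARTER mRNA-Seq kit. The values are FPKM (fragments mapped to a gene, scaled by its length and by the library's mapped total), made by the authors and deposited with 2 decimals in 1 table with 1 column per library, per the file headers. Per the submitters' processing notes, HISAT, StringTie and the GRCm38 genome were used, and their versions, parameters, annotation release and use of strand are not given in the sources used here. FPKM divides by each library's total, so a library in which a few genes take a large share shows lower values for all others. Without counts the depth per library is unknown and no counting interval can be given. The low values were searched for steps worth 1 read, and at best 22.4% to 25.6% of them per library lay on a common step (within 0.1 of a whole multiple) against 20% by chance, so no read numbers were recovered. Without stated strand, reads of overlapping antisense genes cannot be told apart, and near-identical paralogs are uncertain.

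Of 25102 genes, 169 were listed at 0 in every library. Coordinates, biotypes and exon lengths came from GENCODE M21 on GRCm38, in which 25051 of the gene identifiers were found. The table held 37 mitochondrially encoded genes. A further 7 nuclear genes were counted as copies of mitochondrial sequence because at least 50% of their 31-base words occur in the mitochondrial genome. No pair of libraries had identical values.

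All work used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Genes with a mean of at least 1 FPKM over the 6 libraries were tested on log2(FPKM + 1) with limma (empirical Bayes with an intensity trend, two-sided, no covariates), with no scaling beyond FPKM, and p-values were adjusted by Benjamini and Hochberg over the 8528 genes at a threshold of 0.05. Sdha, Sdhb and the other genes of the title also had an exact two-sided permutation test of the 3 against 3 libraries, whose smallest possible p is 0.1. The 45 gene lists (cell types, zones, pathways and complexes) were tested with limma camera at a preset inter-gene correlation of 0.01 where at least 5 members were tested, which held for 35 lists, with adjustment over these lists. Beside it stood camera with the correlation estimated per list and limma's fry. With an estimated correlation 0 of the 18 calls held (smallest adjusted p = 0.119, 2 lists at an unadjusted p under 0.05), and with fry 0 held (smallest adjusted p = 0.497).

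The test, filter, pseudocount, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named the 4 SDH subunits, Cul1, Nedd8, Yap1 and Wwtr1 whatever their values. It then took the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with a mean of at least 5 FPKM in 1 group and no overlap between the groups, leaving out predicted or clone-named genes (17 of the genes that rose and 15 of those that fell), pseudogenes and variable segments. Of each list it named up to 4 members past the threshold, and where fewer than 2 passed, also the 2 with the highest mean. Some genes that the rule names are not reported here. Genes printed outside this rule were chosen after their values were seen: Lcn2, Glul, Cyp7a1, Cyp2a5, Afp, Gpc3, Col1a1, Col3a1, Acta2, Clec4f, Mki67, Top2a, Xist, Eif2s3y, Acadsb, Rian, Mirg, Dlk1, Rtl1, mt-Co1, mt-Nd1 and the members counted over a list alone.

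The alternatives were pseudocounts of 0.1 and 0.01, no filter, a filter at 5 FPKM, median-ratio scaling, rescaling to TPM, quantile normalization, limma without the trend, with array weights, with the replicate number as a block and against a fold change of 1.5, each library left out in turn, and the 2 other list tests. Added after the data were seen were median-ratio scaling together with leaving out each library, and leaving out mitochondrial genes and their copies. The array weights were 1.50, 0.63 and 11.2 for control replicates 1, 2 and 3. They were 3.58, 0.42 and 0.062 for DEN+CCl4 replicates 1, 2 and 3. Results with array weights thus rest mostly on control replicate 3 and on DEN+CCl4 replicate 1, the treated library closest to the controls.

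The gene test was tested on simulated data for the DEN+CCl4 against control comparison, with 8528 genes of which 200 were changed. It recovered 47% of 4-fold and 97% of 16-fold changes and called 12 unchanged genes. With treated library 3 scaled down as seen here it recovered 43% and 92% and called 45 unchanged genes, 30 of them lower, and with median-ratio scaling 51% and 91% with 2 unchanged genes called. In a simulation of the list test, camera called 0 of 20 unshifted and 5 of 5 shifted lists. The simulated genes varied independently and the lists were drawn at random. The simulation therefore could not test the preset correlation for lists whose genes vary together. Each simulated gene also had the same spread in both groups, so the wider spread of the treated libraries was not simulated. The numbers of unchanged genes called may thus differ in the real data. No sample or column was left out.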

Results

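Poly(A) RNA was sequenced from 6 livers of male C57BL/6J mice, 3 given diethylnitrosamine and carbon tetrachloride (DEN+CCl4) and 3 controls. Diethylnitrosamine is a carcinogen that hepatocytes activate to a DNA-alkylating agent, and carbon tetrachloride injures hepatocytes after activation by Cyp2e1. Repeated doses lead to fibrosis and, after diethylnitrosamine, to hepatocellular carcinoma. Per the labels, the treated mice received DEN once at 1 mg/kg and, about 6 weeks later, CCl4 at 0.2 mL/kg, injected 2 times a week over at most 14 weeks. The labels do not say whether a library came from a tumour, from the surrounding liver or from both. They name no animal beyond a replicate number, so the p-values measure the spread between these samples. Expression was given as FPKM for 25102 genes, of which 8528 had a mean of at least 1 FPKM and were tested. Read depth is unknown, because the table holds no counts.

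DEN+CCl4 replicate 1 lay closer to the controls than replicates 2 and 3 did. Across tested genes, Pearson's r of log2 values (genes are not independent replicates) was 0.919 to 0.964 among the controls and 0.948 to 0.962 between DEN+CCl4 replicate 1 and the controls. It was 0.823 to 0.870 between replicate 2 and the controls, and 0.744 to 0.779 between replicate 3 and the controls. The first principal component held 66.0% of the variance. Mitochondrially encoded transcripts and 7 nuclear copies of them took 85.0% of the FPKM of DEN+CCl4 replicate 3. They took 38.1%, 62.1% and 46.5% in control replicates 1, 2 and 3 and 52.3% and 56.7% in DEN+CCl4 replicates 1 and 2. The median tested gene stood at 1.19 FPKM in DEN+CCl4 replicate 3 and at 3.43 to 4.46 FPKM in the other 5 libraries. In it 16447 genes were above 0, against 19260 to 20634 elsewhere. The median log2 fold change of all tested genes was -0.27 (0.12 without this library, and 0.01 after each library was divided by its median ratio to the geometric mean, here called median-ratio scaling). The list medians below are given relative to the median of all genes.

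The comparison of DEN+CCl4 with control liver asked which transcripts differ in this model of hepatocellular carcinoma. Female-biased and fetal liver transcripts were among those that rose most, and P450 genes among those that fell most. Cyp2a4, a female-biased steroid hydroxylase (chromosome 7, 26307169 to 26315088, GRCm38), rose from 2.44 ± 1.06 to 307 ± 275 FPKM (SD, n = 3), a log2 fold change of 5.85 (limma adjusted p = 3.92e-07). The long noncoding RNA H19 (chromosome 7, 142575529 to 142578143), an imprinted transcript abundant in fetal liver and silenced after birth, read 0, 0 and 0.09 FPKM in the controls and 2.61, 37.1 and 23.4 FPKM in DEN+CCl4 liver (log2 fold change 3.86, limma adjusted p = 5.30e-08). In the other direction, Cyp2e1, the enzyme that activates both compounds, fell from 1626 ± 775 to 303 ± 436 FPKM (log2 fold change -4.49, limma adjusted p = 0.00885). Oat, the ornithine aminotransferase of the hepatocytes around the central vein, fell from 148 ± 73.4 to 14.2 ± 20.7 FPKM (log2 fold change -4.25, limma adjusted p = 0.00185).

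In all, 71 genes were higher and 55 lower in DEN+CCl4 liver, each with a log2 fold change of at least 1 in size. Fold changes are on the log2(FPKM + 1) scale and so understate the change of low genes. The 3 values of each group did not overlap for 60 of the 71 and 29 of the 55, and for 8.36% of all tested genes, against 10% by chance (14.2% after median-ratio scaling). After Cyp2a4, the named genes with the largest rises were Akr1c18, a progesterone-metabolising aldo-keto reductase (0.1 ± 0.1 against 57.1 ± 75.4 FPKM, log2 fold change 4.82), the female-biased Cyp2b9 (4.09), the cell surface gene Ly6d (3.97) and H19. They were followed by the apolipoprotein gene Apoa4 (46.3 ± 11.4 against 893 ± 790 FPKM, 3.81), Ifi27l2b (3.47), the p53 target Psrc1 (2.80), the tetraspanins Cd63 (2.67) and Tspan8 (2.36), Fhl3 (2.28) and the imprinted noncoding RNA Meg3 (2.25). Among named genes whose groups did not overlap, the largest falls were in the P450 genes Cyp2c37 (-4.32), Cyp4a10 (-4.05), Cyp2c54 (-4.00), Cyp2c50 (-3.83), Cyp4a14 (-3.40), Cyp8b1 (-3.32) and Cyp4a32 (-2.99). Outside that family they were in the major urinary protein gene Mup21 (-4.10), in Oat, in the lipid droplet gene Fitm1 (33.3 ± 14.2 against 1.57 ± 1.63 FPKM, -3.89), in Lhpp, a histidine phosphatase gene (-3.25), and in the growth factor gene Fgf1 (-2.66). Limma adjusted p ran from 3.22e-09 for Akr1c18 to 0.0288 for Apoa4 over these 24 genes. P450 genes made up 12 of the 55 that fell and 2 of the 71 that rose. Of the Mup genes, 16 of the 18 tested fell. Members of the Mup, Cyp2a, Cyp2c and Cyp4a families are near-identical copies whose reads may be split by the counting, so single members are uncertain. Cyp2a5, the close copy of Cyp2a4, read 552 ± 191 FPKM in controls and 160 ± 163 FPKM in DEN+CCl4 liver (log2 fold change -2.30, limma adjusted p = 0.521).

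The number of calls rose without DEN+CCl4 replicate 1 and fell when any other library was left out. Without DEN+CCl4 replicate 3, the library with the high mitochondrial share, 0 genes passed limma's test (522 higher and 139 lower at an unadjusted p under 0.05, smallest adjusted p = 0.0572). After median-ratio scaling 0 passed (468 and 446 at an unadjusted p under 0.05, smallest adjusted p = 0.198). All 126 genes kept their sign in both, and 114 stayed at an unadjusted p under 0.05 after median-ratio scaling. The 126 were selected for their differences in these same libraries, so this is no independent support for them. Their fold changes stayed about as large after that scaling: the median was 1.81 before and 2.01 after for the 71 that rose, and -3.32 and -3.16 for the 55 that fell. Their median standard error went from 0.42 to 0.68 and from 0.82 to 0.90. The counts were 109 higher and 270 lower without DEN+CCl4 replicate 1, 38 and 15 without DEN+CCl4 replicate 2, and 13 and 10, 8 and 6, and 10 and 9 without control replicates 1, 2 and 3. Cyp2a4, Akr1c18, Cyp2b9, Ly6d, H19 and Fitm1 were the 6 of 35 named genes past the threshold that kept it when any library other than DEN+CCl4 replicate 3 was left out. Without that replicate their limma adjusted p was 0.273, 0.260, 0.510, 0.391, 0.439 and 0.0861.

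**Figure D1:**
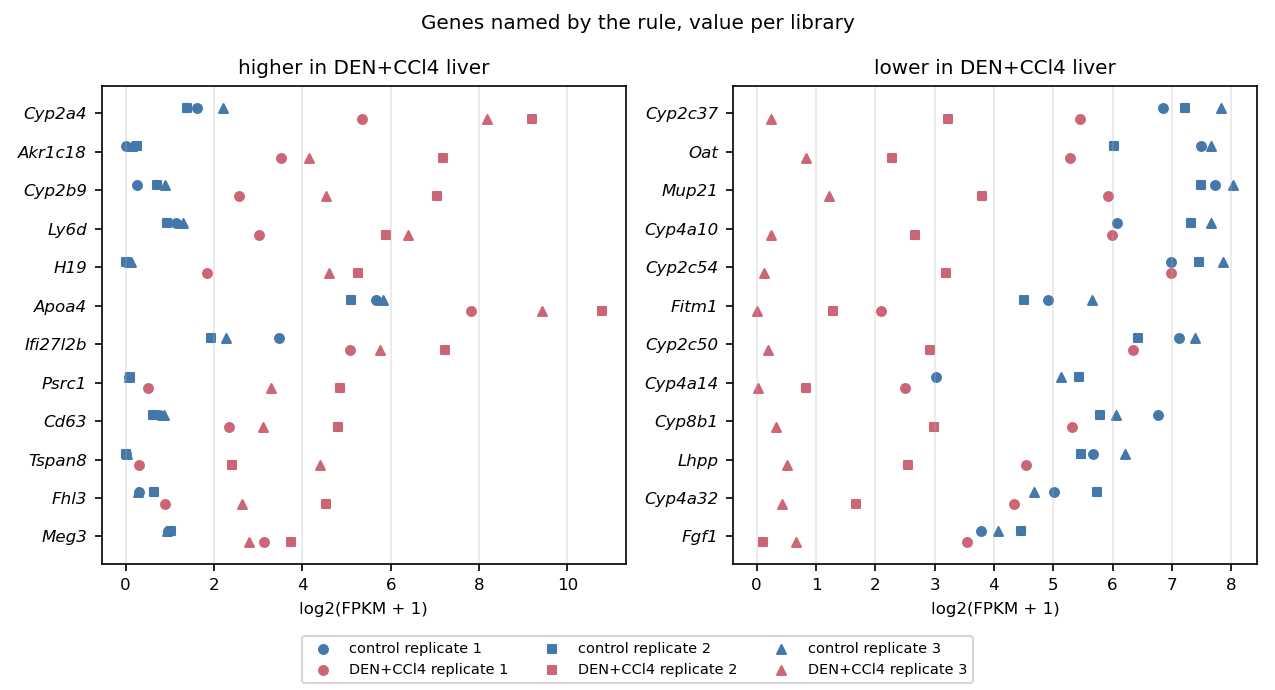
Expression as log2(FPKM + 1) of the 24 genes named for the largest rises and falls among those whose groups do not overlap, 1 point per library, for 3 control and 3 DEN+CCl4 livers. Log2 fold changes run from 5.85 for Cyp2a4 to -4.32 for Cyp2c37.

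The list of genes that mark liver tumours and fetal liver shifted higher with the preset correlation (limma camera adjusted p = 4.59e-49), though not with an estimated correlation (adjusted p = 0.119) or with fry (0.497). Of the 13 tested members, 9 were higher in DEN+CCl4 liver and 0 lower (12 and 0 when adjusted over the list alone). All 13 had a positive log2 fold change. Members near 0 in controls could reach the filter only by being high in DEN+CCl4 liver, which leans these counts and the list test to the higher direction. Of all 20 members in the table, filtered or not, 20 had a higher mean in DEN+CCl4 liver. Of these, 14 lay above all controls in all 3 libraries. Afp, the fetal serum protein used as a tumour marker, rose from 0.187 ± 0.0635 to 5.77 ± 4.70 FPKM (SD, n = 3; log2 fold change 2.06, limma adjusted p = 0.00207). The oncofetal proteoglycan gene Gpc3 rose from 0.0367 ± 0.0351 to 2.59 ± 2.15 FPKM (1.57, limma adjusted p = 0.00737). Afp was 8.27 and 8.69 FPKM in DEN+CCl4 replicates 2 and 3 and 0.34 FPKM in replicate 1, against 0.15 to 0.26 FPKM in the controls. Lcn2, a secreted siderophore-binding protein also made in acute phase responses, was at 149, 1.20 and 1.67 FPKM in controls and 79.7, 49.3 and 159 FPKM in DEN+CCl4 liver (limma adjusted p = 0.0503). The list's median stood 2.33 above that of all genes on the log2 scale. Per library, after median-ratio scaling, the list's median was 0.48, 2.26 and 3.24 above the control mean in DEN+CCl4 replicates 1, 2 and 3.

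Targets of the tumour suppressor p53 shifted higher with the preset correlation (limma camera adjusted p = 3.02e-06), though not with an estimated correlation (adjusted p = 0.554) or with fry (0.688). Of 16 tested members 3 rose and 0 fell, the same adjusted over the list alone (3 and 0). Cdkn1a, the cell cycle inhibitor p21, went from 0.517 ± 0.154 to 7.04 ± 6.29 FPKM (SD, n = 3; log2 fold change 2.03, limma adjusted p = 0.00882). Phlda3, an inhibitor of Akt signalling, went from 0.360 ± 0.113 to 3.44 ± 2.41 FPKM (1.52, limma adjusted p = 0.0336). The third was Psrc1, a microtubule-binding gene, at 0.06 ± 0.01 and 12.4 ± 14.2 FPKM. The list's median was 0.79 above all genes. Without DEN+CCl4 replicate 3 the list no longer passed (limma camera adjusted p = 0.0954), nor with array weights (0.480).

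The list of hepatocyte genes of the pericentral zone, the cells around the central vein that carry most drug metabolism, shifted lower with the preset correlation (limma camera adjusted p = 1.14e-20), though not with an estimated correlation (adjusted p = 0.554) or with fry (0.584). All 19 tested members had a negative log2 fold change, and 7 of them fell and 0 rose (14 and 0 when adjusted over the list alone). The list's median lay -2.18 from that of all genes. Besides Cyp2e1 and Oat, Cyp2c37 fell from 163 ± 58.0 to 17.2 ± 22.7 FPKM (SD, n = 3) and Cyp2c50 from 130 ± 41.0 to 28.9 ± 44.3 FPKM. Glul, the glutamine synthetase of the innermost ring of hepatocytes, measured 148 ± 32.4 and 39.8 ± 52.7 FPKM (log2 fold change -3.03, limma adjusted p = 0.105). Cyp2e1 read 804, 103 and 2.39 FPKM in DEN+CCl4 replicates 1, 2 and 3, against 1885, 755 and 2239 FPKM in the controls. As deposited, 9, 19 and 19 of the 19 genes lay below all 3 controls in DEN+CCl4 replicates 1, 2 and 3. Most tested genes of any kind were lower in DEN+CCl4 replicate 3 as deposited, so its count may partly reflect the scale of that library. After median-ratio scaling the list's median was -0.70, -2.58 and -3.13 from the control mean in DEN+CCl4 replicates 1, 2 and 3. Periportal hepatocyte genes, which serve urea and glucose production around the portal vein, had a median -0.80 from all genes (limma camera adjusted p = 0.173; adjusted p = 0.902 with an estimated correlation). Of its 20 members 1 was higher, Apoa4, and 0 were lower. When adjusted over the list alone 1 was higher and 2 were lower, Cyp2f2 and Etnppl, named after their values were seen. Pck1, of gluconeogenesis, was at 764 ± 191 and 401 ± 412 FPKM. The periportal list passed in the lower direction without DEN+CCl4 replicate 1 (limma camera adjusted p = 0.0286) and with no filter on low values (0.0160).

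Of 34 tested cytochrome P450 genes, which oxidise drugs, steroids and fatty acids, 9 fell and 2 rose (21 and 2 when adjusted over the list alone). Their median lay -2.07 from all genes (limma camera adjusted p = 1.98e-12; adjusted p = 0.596 with an estimated correlation). Those that rose were the female-biased Cyp2a4 and Cyp2b9. Genes of bile acid synthesis and transport had 2 of 23 members lower and 0 higher (12 lower and 1 higher, Slc51b, when adjusted over the list alone). Their median lay -1.26 from all genes (limma camera adjusted p = 1.37e-09; adjusted p = 0.596 with an estimated correlation). Cyp8b1, the sterol 12-hydroxylase that sets cholic acid output, fell from 75.6 ± 28.0 to 15.3 ± 20.6 FPKM (SD, n = 3; log2 fold change -3.32, limma adjusted p = 0.0209). The sinusoidal uptake carrier Slco1a4 fell from 6.14 ± 1.33 to 1.07 ± 1.45 FPKM (-1.99, limma adjusted p = 0.0174). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, read 10.2 ± 2.48 and 6.46 ± 9.41 FPKM (-1.52, limma adjusted p = 0.425), with 17.3, 2.12 and 0 FPKM in DEN+CCl4 replicates 1, 2 and 3.

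The lists of male-biased and female-biased liver genes shifted in opposite directions with the preset correlation (limma camera adjusted p = 1.71e-17 and 6.35e-15). They did not pass with an estimated correlation (adjusted p = 0.554 and 0.119) or with fry (0.584 and 0.497). Of the male-biased genes, which pulsatile growth hormone keeps high in males, 6 of 19 tested fell and 0 rose (14 and 0 when adjusted over the list alone). Their median lay -2.12 from all genes. The pheromone carrier gene Mup7 read 6950, 3022 and 4898 FPKM in controls and 5519, 181 and 8.54 FPKM in DEN+CCl4 replicates 1, 2 and 3 (log2 fold change -4.46, limma adjusted p = 0.00648). Mup1 (-4.43, limma adjusted p = 0.0103), Mup21 and the steroid dehydrogenase Hsd3b5 (-2.92, limma adjusted p = 0.0223) fell as well. After median-ratio scaling the list's median was 0.09, -2.74 and -3.57 from the control mean in DEN+CCl4 replicates 1, 2 and 3. Of the female-biased genes, 2 of 5 tested rose and 0 fell (2 and 0 when adjusted over the list alone). The median of these 5 stood 1.21 above all genes. Members near 0 in controls could reach the filter only by being high in DEN+CCl4 liver. Of the 15 members in the table, filtered or not, 14 had a higher mean there, and 7 lay above all controls in all 3 libraries. The 2 that rose were Cyp2a4, at 40.1, 590 and 290 FPKM in DEN+CCl4 replicates 1, 2 and 3, and Cyp2b9. Xist, the noncoding RNA of the inactive X chromosome, looked up after these values were seen, was between 0 and 0.02 FPKM in all 6 libraries. The Y-linked Eif2s3y was between 1.47 and 4.67 FPKM, and every mouse was labelled male.

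Mitochondrial and other metabolic genes of hepatocytes formed the other 6 lists that shifted lower with the preset correlation, with 0 members past the threshold over all genes. None passed with an estimated correlation (adjusted p = 0.670 to 0.902) or with fry (0.584 for each). The 36 tested subunits of respiratory complex I, all nuclear-encoded, had 0 called members over all genes and 0 adjusted over the list alone. All 36 log2 fold changes were negative, with a median -0.85 from all genes (limma camera adjusted p = 0.000102; adjusted p = 0.886 with an estimated correlation). Per library, after median-ratio scaling, the complex I median stood at 0.02, -0.96 and -1.07 from the control mean in DEN+CCl4 replicates 1, 2 and 3, and at -0.41 in control replicate 2, the control with the largest mitochondrial share (62.1%). Ndufa6 was at 178 ± 69.6 FPKM in controls and 89.7 ± 75.2 FPKM in DEN+CCl4 liver (SD, n = 3), and Ndufa8 at 109 ± 22.5 and 75.7 ± 57.5 FPKM. Nuclear-encoded subunits of complexes III, IV and V (30 tested, 0 called over all genes, 0 adjusted over the list alone) had a median -0.99 from all genes (limma camera adjusted p = 7.16e-05; adjusted p = 0.886 with an estimated correlation). Cox6a1 was at 524 ± 230.1 and 232 ± 249.9 FPKM and Uqcr11 at 337 ± 97.9 and 151 ± 144 FPKM. The other citric acid cycle enzymes (15 tested, 0 called, 0 adjusted over the list alone) had a median -0.57 from all genes (limma camera adjusted p = 0.0305; adjusted p = 0.902 with an estimated correlation). Among them Pcx, pyruvate carboxylase, measured 39.0 ± 4.67 and 27.0 ± 16.4 FPKM. Leaving out DEN+CCl4 replicate 2 ended the call for complexes III, IV and V (limma camera adjusted p = 0.0567). Leaving out control replicate 1, control replicate 3 or DEN+CCl4 replicate 2 ended that for the citric acid cycle (limma camera adjusted p = 0.0715, 0.0800 and 0.154), as did requiring a mean of at least 5 FPKM (0.159).

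Fatty acid oxidation genes (24 tested, 0 called, 0 adjusted over the list alone) had a median -0.79 from all genes (limma camera adjusted p = 0.000130; adjusted p = 0.886 with an estimated correlation). The peroxisomal thiolase Acaa1b was at 179.9 ± 47.7 FPKM in controls and 114 ± 98.4 FPKM in DEN+CCl4 liver (SD, n = 3). Genes of gluconeogenesis and amino acid catabolism (19 tested, 0 called over all genes, 4 lower and 0 higher adjusted over the list alone, among them Bhmt, Hpd and Cth) had a median -1.73 from all genes (limma camera adjusted p = 7.53e-08; adjusted p = 0.670 with an estimated correlation). Hpd, of tyrosine breakdown, measured 1121 ± 156 and 476 ± 623 FPKM, and Tat, the tyrosine aminotransferase, 854 ± 178 and 371 ± 443 FPKM. For the urea cycle (10 tested, 0 called over all genes, 1 lower adjusted over the list alone, the aspartate-glutamate carrier Slc25a13) the median lay -1.10 from all genes (limma camera adjusted p = 0.00223; adjusted p = 0.765 with an estimated correlation). Ass1 was at 578 ± 121 and 261 ± 347 FPKM and Arg1 at 284 ± 65.1 and 184 ± 136 FPKM. With array weights the urea cycle call was lost (limma camera adjusted p = 0.128), and with a mean of at least 5 FPKM required as well (0.103).

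The lists of extracellular matrix genes and of the cells that make it shifted higher with the preset correlation, with 0 members past the threshold over all genes. Neither passed with an estimated correlation (adjusted p = 0.554 and 0.594) or with fry (0.584 for both). All but 1 of the 14 tested matrix genes had a positive log2 fold change. Here too, members low in controls reached the filter only if high in DEN+CCl4 liver. Of the 30 matrix genes in the table, filtered or not, 29 had a higher mean there. Over all genes tested 0 passed, and 1 was higher when adjusted over the list alone, Col1a1. The list's median was 0.71 above all genes (limma camera adjusted p = 1.68e-07). It was 0.35, 0.55 and 1.56 above the control mean in DEN+CCl4 replicates 1, 2 and 3 after median-ratio scaling. Col1a1, the main fibrillar collagen of scar, was at 0.787 ± 0.184 FPKM in controls and 4.23 ± 2.70 FPKM in DEN+CCl4 liver (SD, n = 3; log2 fold change 1.43, limma adjusted p = 0.123). Col3a1 was at 1.15 ± 0.0603 and 4.69 ± 3.35 FPKM, and both genes lay above all controls in all 3 DEN+CCl4 libraries. The members with the highest levels differed less. Fn1, fibronectin, measured 32.2 ± 11.4 and 41.8 ± 11.3 FPKM, and Bgn, biglycan, 8.48 ± 2.11 and 9.50 ± 3.34 FPKM. Markers of hepatic stellate cells and myofibroblasts (10 tested, 0 called, 0 adjusted over the list alone) had a median 0.58 above all genes (limma camera adjusted p = 0.00278; 0.146 with no filter on low values). Acta2, the smooth muscle actin of activated stellate cells, was at 1.37 ± 0.258 and 5.87 ± 4.35 FPKM. Ecm1 (42.2 ± 24.8 and 24.1 ± 13.8 FPKM) and the stellate cell lectin Colec11 (5.91 ± 1.29 and 5.82 ± 1.47 FPKM) stood highest. Markers of sinusoidal endothelium (11 tested, 0 called, 0 adjusted over the list alone) had a median 0.44 above all genes (limma camera adjusted p = 0.0389; adjusted p = 0.886 with an estimated correlation). Clec4g was at 6.50 ± 1.87 and 6.46 ± 3.59 FPKM and Stab1 at 3.64 ± 1.46 and 6.71 ± 3.55 FPKM. Leaving out control replicate 1, control replicate 3 or DEN+CCl4 replicate 1 ended the sinusoidal call (limma camera adjusted p = 0.0626, 0.175 and 0.0696), as did rescaling to TPM (0.0525).

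Of 19 tested genes of the endoplasmic reticulum stress response, 1 rose and 0 fell (1 and 0 when adjusted over the list alone). The list's median was 0.62 above all genes (limma camera adjusted p = 1.26e-05; adjusted p = 0.596 with an estimated correlation; 0.106 with array weights and the preset correlation). The member that rose was Fgf21, a secreted hepatokine (0.533 ± 0.420 and 4.85 ± 4.64 FPKM, SD, n = 3; log2 fold change 1.58, limma adjusted p = 0.0480). Herpud1 (169 ± 60.3 and 114 ± 96.9 FPKM) and Atf4 (44.6 ± 7.59 and 51.2 ± 33.5 FPKM) were the most abundant. Of 13 immediate early genes, which respond within minutes to growth factors, stress and tissue handling, 1 rose and 0 fell (1 and 0 when adjusted over the list alone). Their median was 0.74 above all genes (limma camera adjusted p = 0.000605; adjusted p = 0.757 with an estimated correlation; 0.108 with the preset correlation and a mean of at least 5 FPKM). Ier3 rose from 0.633 ± 0.221 to 7.19 ± 5.35 FPKM (log2 fold change 2.05, limma adjusted p = 0.01003). Zfp36 was at 96.8 ± 66.4 and 71.2 ± 54.4 FPKM and Junb at 26.7 ± 14.9 and 56.6 ± 31.1 FPKM.

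**Figure D2:**
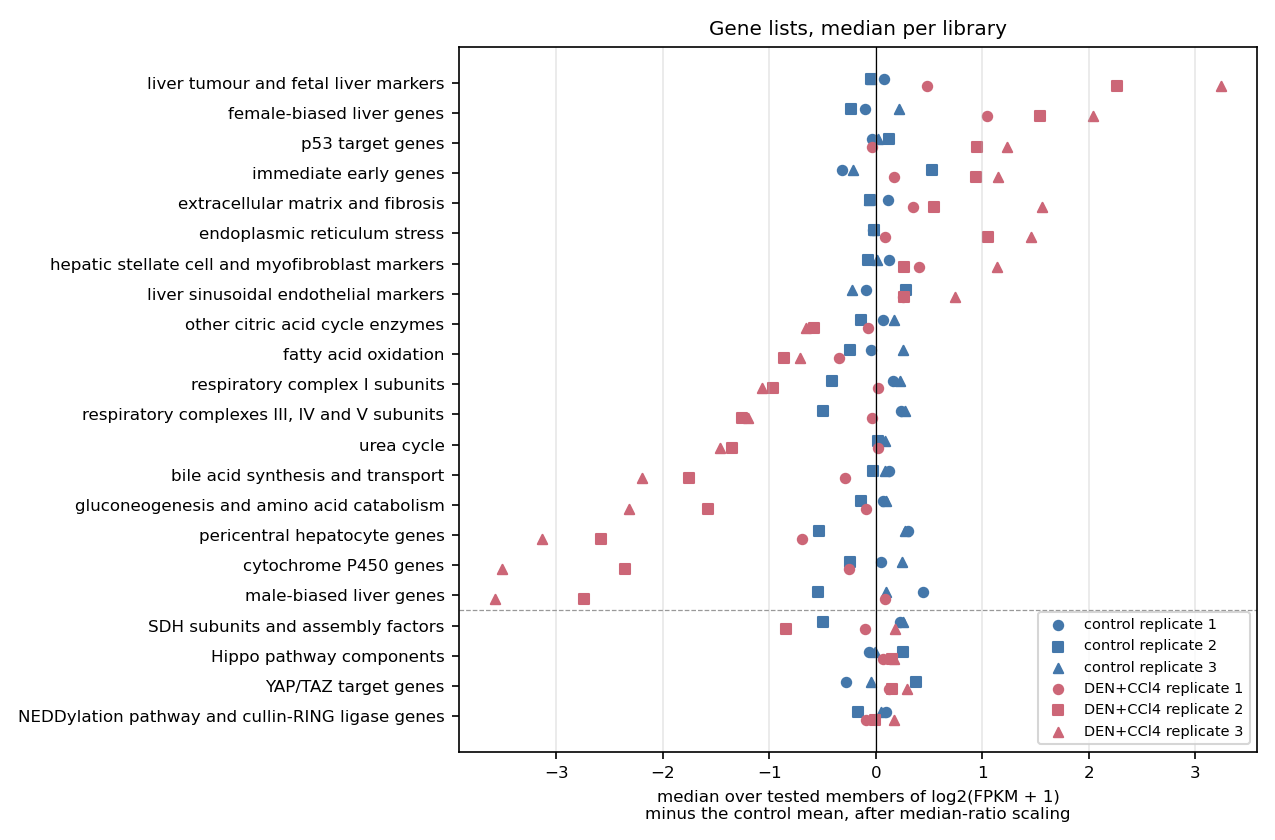
Median log2 difference from the control mean, after median-ratio scaling, of the members of each gene list in each of the 3 control and 3 DEN+CCl4 livers, 1 point per library, with the 18 lists that passed limma camera's test with the preset correlation above the dashed line and 4 lists of the study's own genes below it. Tumour and fetal markers stand at 0.48, 2.26 and 3.24 and pericentral genes at -0.70, -2.58 and -3.13 in DEN+CCl4 replicates 1, 2 and 3.

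Other programs of hepatocytes did not pass the list test. Acute phase proteins (16 tested) had a median -0.35 from all genes (limma camera adjusted p = 0.630). The iron hormone Hamp was at 3569 ± 1417 and 1957 ± 2229 FPKM and the haemoglobin scavenger Hp at 2125 ± 1974 and 1651 ± 1489 FPKM (SD, n = 3). Control replicate 1 stood 1.49 above the control mean in this list after median-ratio scaling, and without it the list passed in the higher direction (limma camera adjusted p = 0.00165), as it did with array weights (0.0122). It passed in the lower direction without control replicate 2, control replicate 3 or DEN+CCl4 replicate 1 (0.0312, 0.0426 and 0.0245). Secreted plasma proteins (20 tested) had a median -0.19 from all genes (limma camera adjusted p = 0.652). After median-ratio scaling that median was 0.003 and the limma camera adjusted p 0.679. Alb, albumin, was at 17540 ± 5269 and 14563 ± 8832 FPKM and Apoa1 at 11833 ± 1074 and 16495 ± 16423 FPKM. Of 21 genes of fatty acid and triglyceride synthesis 1 rose and 0 fell (median 0.31 above all genes; limma camera adjusted p = 0.138). It was Pnpla3, a lipid droplet acyl hydrolase, at 0.04 ± 0.0265 and 5.12 ± 7.74 FPKM (limma adjusted p = 0.00609). Without DEN+CCl4 replicate 3 this list passed (limma camera adjusted p = 0.0228). Cholesterol synthesis (22 tested, -0.06 from all genes, 0.03 after median-ratio scaling; limma camera adjusted p = 0.953), glycolysis (16 tested, -0.11; 0.958), hypoxia-induced genes (12 tested, -0.13; 0.953), circadian clock genes (12 tested, -0.24; 0.506) and NRF2 targets with glutathione metabolism (21 tested, -0.11, and 0.08 after median-ratio scaling; 0.421) had 0 called members each. The cholesterol list passed in the lower direction with array weights (limma camera adjusted p = 0.00211). The NRF2 list passed in the higher direction without DEN+CCl4 replicate 2 (limma camera adjusted p = 0.00963). Adjusted over the list alone, 2 NRF2 list members were higher, Cbr3 and Gsta1, and 1 member of the fatty acid and triglyceride list, Pnpla3, with 0 in the acute phase, secreted protein, cholesterol, glycolysis, hypoxia and clock lists. The NRF2 list had a negative median (-0.38) and mean (-0.28) log2 fold change beside a test in the higher direction. The fatty acid and triglyceride list had a positive median (0.04), a negative mean (-0.09) and a test in the higher direction.

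Most markers of neutrophils, recruited macrophages and T cells had a higher mean in DEN+CCl4 liver, and 1 of them passed. It was S100a8, a calcium-binding protein of neutrophils, which rose from 0.507 ± 0.223 to 4.51 ± 3.96 FPKM (SD, n = 3; log2 fold change 1.63, limma adjusted p = 0.0336), the 1 called gene among 3 tested neutrophil markers. S100a9 was at 2.27 ± 1.28 and 8.93 ± 4.66 FPKM. The immunoglobulin light chain Igkc of plasma cells was at 81.4 ± 9.74 and 313 ± 231 FPKM (log2 fold change 1.70, limma adjusted p = 0.838), above all controls in all 3 DEN+CCl4 libraries. Ighm was at 4.86 ± 0.312 and 16.8 ± 11.9 FPKM, with 0 of 4 tested B and plasma cell markers called. Adjusted over the list alone, 2 neutrophil markers were higher (S100a8 and S100a9), 1 adipose marker was lower (Car3, a carbonic anhydrase that hepatocytes also express) and 1 cell cycle gene was lower (Tk1). None passed in the T cell, NK cell, B and plasma cell, recruited macrophage, cholangiocyte, capillary endothelial and pancreas lists. All these lists had under 5 tested members and so no list test. All 11 neutrophil markers in the table, 12 of 15 recruited monocyte and macrophage markers and 11 of 14 T cell markers had a higher mean in DEN+CCl4 liver. Of these, 2, 7 and 6 lay above all controls in all 3 libraries. The 10% by chance counts groups that do not overlap either way, so the chance share for the higher direction alone is lower. Most of these markers were under the filter, with control medians of 0.15, 0.17 and 0.17 FPKM over the lists, near the floor. The recruited macrophage markers Lyz2 and Cd68 read 10.3 ± 8.88 and 11.8 ± 3.16 FPKM, and 6.58 ± 3.72 and 6.91 ± 4.02 FPKM, in control and DEN+CCl4 liver. T cell receptor genes Trbc2 and Trac were at 2.49 ± 0.429 and 5.59 ± 2.95 FPKM, and 1.16 ± 0.451 and 1.21 ± 0.662 FPKM. The cytotoxic cell genes Nkg7 and Gzmb were at 0.977 ± 0.0503 and 1.67 ± 0.301 FPKM, and 0.147 ± 0.115 and 0.307 ± 0.197 FPKM (1 tested NK marker).

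Kupffer cell markers, those of the resident macrophages, had a median -0.21 from all genes (9 tested, 0 called, 0 adjusted over the list alone; limma camera adjusted p = 0.341). The complement gene C1qa was at 29.7 ± 18.5 and 23.4 ± 16.3 FPKM and C1qb at 24.0 ± 14.3 and 24.1 ± 6.19 FPKM (SD, n = 3). Clec4f, a lectin found on Kupffer cells, was at 27.7 ± 11.4 and 11.1 ± 9.08 FPKM. Of the 11 Kupffer markers in the table, 1 had a higher mean in DEN+CCl4 liver and 4 lay below all controls in all 3 libraries. This list passed in the lower direction without control replicate 3 (limma camera adjusted p = 0.0430) and DEN+CCl4 replicate 3 (0.0464), and with no filter on low values (0.00320). Red cell genes (5 tested, median 0.79 above all genes; limma camera adjusted p = 0.303), MHC class II and antigen presentation (6 tested, 0.30; 0.401) and interferon-stimulated genes (13 tested, 0.20; 0.439) had 0 called members over all genes and 0 adjusted over the list alone. The MHC class II list passed in the higher direction with quantile normalization (limma camera adjusted p = 0.0278). The interferon list had a raw median of -0.07 and mean of -0.09 beside a test in the higher direction. The haemoglobin genes Hba-a1 and Hba-a2, near-identical copies, were at 129 ± 50.1 and 349 ± 446 FPKM, and 130 ± 54.5 and 349 ± 448 FPKM, with Hba-a2 at 863 FPKM in DEN+CCl4 replicate 2. Cd74 and H2-Eb1, of antigen presentation, were at 43.5 ± 36.7 and 26.9 ± 9.16 FPKM, and 25.4 ± 3.49 and 34.6 ± 12.1 FPKM. The interferon-stimulated Bst2 and Isg15 were at 70.6 ± 36.5 and 52.1 ± 43.0 FPKM, and 6.50 ± 0.716 and 9.42 ± 5.79 FPKM.

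Among proliferation genes, 4 of 35 reached the filter, too few for a list test. The cell cycle term of the deposited annotation (64 tested, 2 higher, 0 lower), looked at after the lists, passed in the higher direction with a median 0.12 above all genes (limma camera adjusted p = 0.0336; adjusted p = 0.997 with an estimated correlation). Ccnd1, cyclin D1, was at 1.64 ± 0.350 FPKM in controls and 7.50 ± 8.32 FPKM in DEN+CCl4 liver (SD, n = 3; log2 fold change 1.23, limma adjusted p = 0.474). Tk1 was at 10.1 ± 2.11 and 3.74 ± 4.37 FPKM. The mitotic genes Top2a (0.0133 ± 0.00577 and 0.113 ± 0.0252 FPKM) and Mki67 (0.0433 ± 0.0351 and 0.207 ± 0.105 FPKM), picked after their values were seen, stayed under the filter. Of the 35 genes, 23 had a higher mean in DEN+CCl4 liver. Cholangiocyte genes were represented by Spp1, osteopontin, at 10.6 ± 3.71 and 21.5 ± 7.59 FPKM (3 tested, 0 called). Capillary endothelium was represented by Plvap at 16.0 ± 5.04 and 15.8 ± 9.002 FPKM and Gja4 at 1.99 ± 0.525 and 1.86 ± 1.18 FPKM (2 tested, 0 called). The pancreas was represented by Cela1 at 6.42 ± 3.29 and 6.77 ± 4.56 FPKM and Cela2a at 0.223 ± 0.200 and 0.323 ± 0.416 FPKM (1 tested, 0 called), and adipose tissue was represented by Car3 at 260 ± 92.1 and 74.9 ± 108 FPKM (log2 fold change -3.52, limma adjusted p = 0.0503) and Plin4 at 5.52 ± 5.41 and 3.31 ± 3.72 FPKM (4 tested, 0 called).

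The title of the series concerns loss of SDHA and SDHB, the catalytic subunits of succinate dehydrogenase (respiratory complex II and the citric acid cycle), NEDDylation of cullin 1 and the Hippo effectors YAP and TAZ in hepatocellular carcinoma. Sdha (chromosome 13, 74322254 to 74350280, GRCm38) had a mean of 14.8 ± 4.64 FPKM in control and 6.67 ± 4.55 FPKM in DEN+CCl4 liver (SD, n = 3), with 11.3, 6.51 and 2.21 FPKM in DEN+CCl4 replicates 1, 2 and 3. Its log2 fold change of -1.20 (SE 0.72; -0.93 relative to all genes, and -0.81 after median-ratio scaling) did not pass (limma adjusted p = 0.827; exact two-sided permutation p = 0.2, where 3 against 3 cannot go under 0.1). Sdhb (chromosome 4, 140961203 to 140979193) had a mean of 48.0 ± 16.4 and 29.0 ± 27.9 FPKM, with 59.9, 21.6 and 5.54 FPKM in DEN+CCl4 replicates 1, 2 and 3. Its log2 fold change of -1.18 (SE 0.91; -0.91 relative to all genes, and -0.74 after median-ratio scaling) did not pass either (limma adjusted p = 0.973; exact two-sided permutation p = 0.3). Both genes lay below all controls in 2 of 3 DEN+CCl4 libraries. Sdhc, at 23.1 ± 9.73 and 13.9 ± 11.96 FPKM (log2 fold change -0.98, limma adjusted p = 0.987), and Sdhd, at 21.9 ± 6.92 and 13.0 ± 4.90 FPKM (-0.72, limma adjusted p = 0.996), the membrane anchors of the complex, had lower means too. The 7 tested SDH subunits and assembly factors (0 called, 0 adjusted over the list alone) had negative log2 fold changes throughout and a median -0.46 from all genes (limma camera adjusted p = 0.258). This list passed in the lower direction without DEN+CCl4 replicate 3 (limma camera adjusted p = 0.0470) and with no filter on low values (0.0164), both with the preset correlation. Over all 6 libraries its limma camera adjusted p was 0.902 with an estimated correlation, and its fry adjusted p was 0.584. The Sdha and Sdhb log2 fold changes were -0.67 and -0.34 without that library and -1.64 and -1.95 without DEN+CCl4 replicate 1. With array weights, which rest mostly on control replicate 3 and DEN+CCl4 replicate 1, they were -0.69 and -0.19.

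Transcripts of the other genes of the title did not pass. Cul1, the cullin of SCF ubiquitin ligases, was at 7.85 ± 0.717 FPKM in control and 5.58 ± 2.84 FPKM in DEN+CCl4 liver (SD, n = 3; log2 fold change -0.54, limma adjusted p = 0.996). Nedd8, the modifier that activates cullins, was at 49.2 ± 27.4 and 25.4 ± 17.7 FPKM (-0.73 relative to all genes, limma adjusted p = 0.996). Yap1 was at 2.63 ± 0.204 and 2.00 ± 2.11 FPKM (-0.49, limma adjusted p = 0.996), with 0.64, 4.43 and 0.93 FPKM in DEN+CCl4 replicates 1, 2 and 3. Wwtr1, which encodes TAZ, was at 1.75 ± 0.362 and 1.83 ± 1.01 FPKM (-0.01, and 0.25 after median-ratio scaling; limma adjusted p = 1.00). Hippo pathway components (9 tested, median 0.01 from all genes; limma camera adjusted p = 0.965) and NEDDylation and cullin-RING ligase genes (23 tested, -0.02, and 0.02 after median-ratio scaling; 0.745) had 0 called members over all genes and 0 adjusted over the list alone. A broader Hippo signaling pathway term of the deposited annotation (71 tested, 2 higher, 1 lower), looked at after the lists, passed in the higher direction with a median 0.21 above all genes (limma camera adjusted p = 0.00621; adjusted p = 0.997 with an estimated correlation). The NEDDylation list passed in the lower direction with array weights (limma camera adjusted p = 0.0203). Wwc1 was at 6.44 ± 1.81 and 5.51 ± 3.24 FPKM, Tead3 at 5.69 ± 2.28 and 4.27 ± 3.10 FPKM, and Rbx1 at 13.1 ± 2.75 and 9.20 ± 5.76 FPKM. YAP/TAZ target genes (8 tested, 0 called, 0 adjusted over the list alone) had a median 0.25 above all genes (limma camera adjusted p = 0.233). They passed in the higher direction without control replicate 2 (limma camera adjusted p = 0.0429), with array weights (0.0414) and with no filter on low values (0.00627), each with the preset correlation. Over all 6 libraries their limma camera adjusted p was 0.886 with an estimated correlation, and their fry adjusted p was 0.912. Their raw median was -0.02 and their mean 0.06, and the test was in the higher direction. Their highest members were Cyr61, a matricellular protein, at 6.47 ± 4.79 and 3.72 ± 2.76 FPKM, and Igfbp3 at 1.71 ± 0.125 and 6.31 ± 5.22 FPKM. NEDDylation and protein stability are not read by transcript levels.

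**Figure D3:**
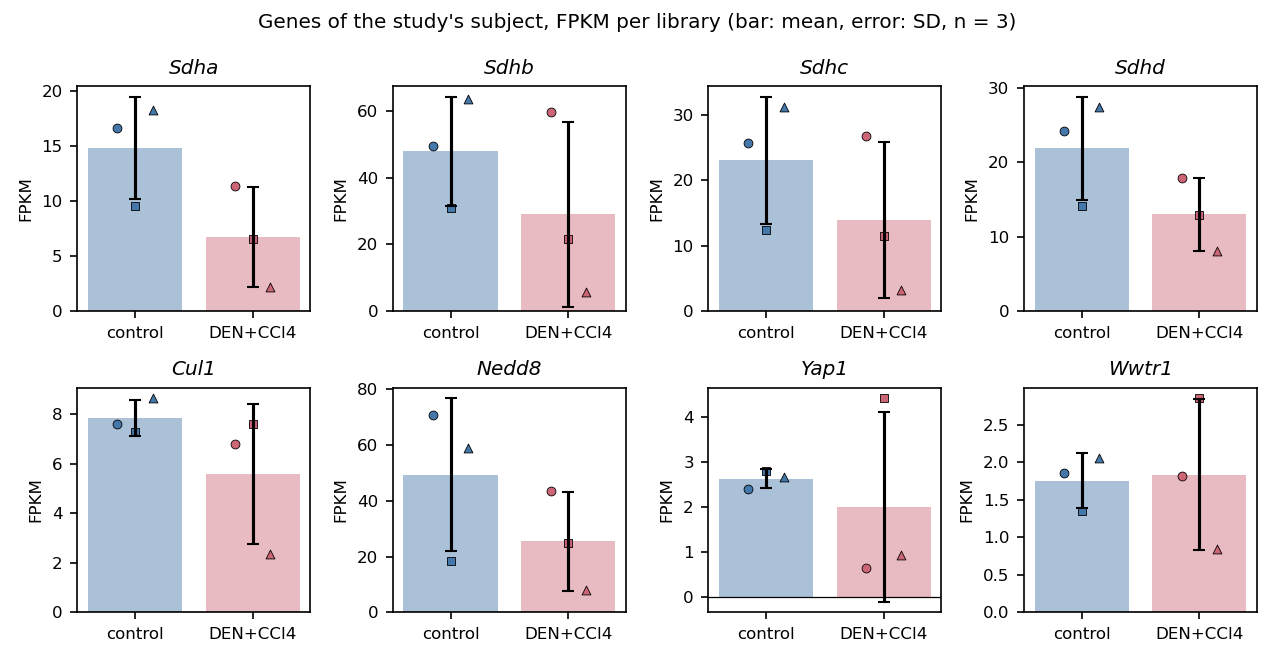
FPKM of Sdha, Sdhb, Sdhc, Sdhd, Cul1, Nedd8, Yap1 and Wwtr1 in 3 control and 3 DEN+CCl4 livers, with bars for the mean, error bars for the SD and a circle, square and triangle for replicates 1, 2 and 3. Sdha averages 14.8 FPKM in control and 6.67 FPKM in DEN+CCl4 liver, and no gene shown passed limma's test.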

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

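All alternatives here were fixed in advance except median-ratio scaling with a library left out and the omission of mitochondrial genes, which were chosen only after the result was seen. Against 71 genes higher and 55 lower, limma gave 6 and 3 with a pseudocount of 0.1, 4 and 0 with 0.01, 0 and 0 with no filter (24933 genes tested), 14 and 53 with a mean of at least 5 FPKM (3321 genes tested), 0 and 0 with median-ratio scaling, 30 and 26 as TPM, 0 and 0 with quantile normalization, 0 and 0 without the trend, 287 and 134 with array weights, 10 and 7 against a fold change of 1.5, 0 and 0 with mitochondrial genes and copies left out, and 0 to 109 higher and 0 to 270 lower with 1 library left out. Of the main calls, 45 of 126 were among those made with array weights, a fit that rests mostly on control replicate 3 and DEN+CCl4 replicate 1. At an unadjusted p under 0.05 the settings with 0 calls gave 540 higher and 568 lower (no filter), 468 and 446 (median-ratio), 413 and 416 (quantile), 131 and 365 (no trend), 487 and 278 (no mitochondrial genes) and 522 and 139 (without DEN+CCl4 replicate 3), against 216 and 432 in the main test. The main calls kept their sign in 126 of 126 genes under each setting that tested all of them, except 125 of 126 without control replicate 1, with or without median-ratio scaling. They were selected in these same libraries, so a kept sign is no independent support. Median-ratio scaling with 1 library left out gave 0 and 0, except 294 and 362 without DEN+CCl4 replicate 1, of which 112 were among the 126. The prior degrees of freedom of the variance were 215 in the main test and 3.66 after median-ratio scaling. In simulated data with equal spread in both groups, a treated library scaled down as here raised the unchanged genes called from 12 to 45. Some of the 126 may therefore be due to the scale of DEN+CCl4 replicate 3. The fold changes of the 126 stayed about as large after median-ratio scaling (median 1.81 before and 2.01 after for those higher, -3.32 and -3.16 for those lower). The calls ended as the median standard error rose (0.42 to 0.68 and 0.82 to 0.90) and the prior degrees of freedom fell, and 114 of the 126 stayed at an unadjusted p under 0.05. What else moved the counts was not tested.

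The replicate block gave 62 genes higher and 32 lower, all among the 126. No clear pairing by replicate number was seen: same-numbered libraries' deviations correlated at 0.07, 0.42 and -0.15, and 2 of the 6 libraries correlated best with their own number. So few pairs cannot exclude a pairing. Lists shifted higher numbered 8, but 15 with no filter (45 lists tested), 3 with a mean of at least 5 FPKM (25 tested), and 0 with an estimated correlation or fry. Lists shifted lower numbered 10, but 0 with an estimated correlation or fry, and no other setting moved either count by over 1.5 times (7 to 9 and 8 to 12 with 1 library left out). All 18 kept their direction in every setting that tested them and their call under median-ratio scaling, and 15 kept the call with array weights. Acute phase proteins, not called (limma camera adjusted p = 0.630, lower), were called higher with array weights (0.0122) and without control replicate 1 (0.00165), over a range of 0.00165 to 0.327 with 1 library left out. Control replicate 1 stood highest of the controls in this list. The first principal component's share of 66.0% was 73.7% at 5 FPKM, 59.2% after quantile normalization and 60.3% to 80.7% with 1 library left out. Sdha and Sdhb stayed negative and unpassed in every setting, from -1.64 to -0.67 and from -1.95 to -0.34 with 1 library left out, and at -0.69 and -0.19 with array weights. Of 109 other named genes, 35 were called and 0 of these changed sign, but all 35 lost the call under median-ratio scaling, with fold changes such as 5.85 before and 6.25 after for Cyp2a4 and -4.32 and -4.20 for Cyp2c37, and without DEN+CCl4 replicate 3. Of the 74 not called, 38 changed sign under at least 1 setting (111 values, the largest 1.11 in size). Leaving out 1 library left 2 in its arm and 3 in the other. Depth is unknown, so what it limits cannot be stated.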

Other observations

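The tests on pathway terms, imprinted genes, swapped labels, an untreated replicate 1 (both marker sets) and the respiratory chain as a class were chosen only after the result was seen. Those on the low FPKM of DEN+CCl4 replicate 3, and on its part in Sdha and Sdhb, address patterns seen in these data. They too were not fixed before the data were examined. Of 3 noncoding RNAs of the imprinted Dlk1-Dio3 cluster on chromosome 12, which are expressed from the maternal chromosome, 1 passed limma's test and 2 had higher means in DEN+CCl4 liver. Meg3 (109541001 to 109571726) rose from 0.970 ± 0.0755 to 8.71 ± 3.34 FPKM (SD, n = 3; log2 fold change 2.25, limma adjusted p = 0.00969), and read 7.76, 12.4 and 5.94 FPKM in DEN+CCl4 replicates 1, 2 and 3. Rian (109603940 to 109661716) was at 0.183 ± 0.0306 and 1.86 ± 1.45 FPKM (log2 fold change 1.14, limma adjusted p = 0.105) and Mirg, under the filter, at 0.123 ± 0.0462 and 1.12 ± 0.588 FPKM. All 3 genes lay above all controls in each of the 3 DEN+CCl4 libraries, replicate 1 included. Of its protein-coding genes, Dlk1 and Rtl1 were looked up and were listed at 0 in the controls and at no more than 0.06 FPKM in DEN+CCl4 liver. Without DEN+CCl4 replicate 3 the limma adjusted p of Meg3 was 0.0572, without DEN+CCl4 replicate 2 it was 0.0516, and without control replicates 1, 2 and 3 it was 0.299, 0.227 and 0.407.

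Of 286 pathway terms of the authors' deposited annotation with 10 to 200 tested genes, 48 were lower and 55 higher by limma camera with the preset correlation, of which 47 and 49 held after median-ratio scaling, and 0 were called with an estimated correlation (smallest adjusted p = 0.997 with an estimated correlation). Peroxisome genes (117 tested) had a median -0.72 from all genes (limma camera adjusted p = 5.68e-09), genes of valine, leucine and isoleucine degradation (62 tested) -0.79 (3.96e-08), those of tryptophan metabolism (39 tested) -0.999 (3.15e-08) and those of linoleic acid metabolism (20 tested, mostly P450 genes) -2.01 (8.06e-12), while cell adhesion molecules (48 tested) lay 0.49 above all genes (2.47e-05). Some called terms cover pathways whose fixed lists did not pass or had no list test: Hippo signaling pathway (71 tested, 0.21 above all genes; limma camera adjusted p = 0.00621, and 0.0130 after median-ratio scaling), its multiple species term (19 tested, 0.30; 0.0152 and 0.0216), cell cycle (64 tested, 0.12; 0.0336 and 0.0118) and, in the lower direction, glutathione metabolism (47 tested, -0.55; 0.0243 and 0.0263). The fixed list of NRF2 targets and glutathione metabolism was tested in the higher direction and did not pass (limma camera adjusted p = 0.421). Acadsb, the short branched-chain acyl-CoA dehydrogenase, fell from 5.26 ± 1.78 to 0.800 ± 0.730 FPKM (SD, n = 3; log2 fold change -1.83, limma adjusted p = 0.0257).

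Most tested genes had lower FPKM in DEN+CCl4 replicate 3, with a median log2 ratio of -1.11 to the mean of the other 5 libraries. Loss of long transcripts is argued against, since Spearman's rho between that ratio and exon length was 0.0557 over 8520 genes (genes are not independent replicates), and rho ran from -0.28 to 0.21 in the other libraries. A larger share of mitochondrial transcripts is a candidate explanation, since with those genes and their nuclear copies left out the median ratio was -0.30. That value lies well above the deposited ratio, so leaving these genes out removed much of the drop. It also lies outside the range of -0.21 to 0.23 in the other 5 libraries. Whether the mitochondrial share is the whole cause, or a further difference of this library adds to it, therefore cannot be told. Whether the mitochondrial share came from the tissue or from its handling was not tested.

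The tumour marker and pericentral changes were larger in DEN+CCl4 replicates 2 and 3 than in replicate 1, where 10, 12 and 12 of 13 tumour and fetal markers lay above all controls in replicates 1, 2 and 3 as deposited. A swap of replicate 1 with a treated liver that responded as replicates 2 and 3 did is argued against, since no control carried the markers. After median-ratio scaling, the highest median log2 difference of a control from the other controls was 0.121. Replicates 2 and 3 stood 2.26 and 3.24 above the control mean. A swapped liver with a weak response could be missed, as replicate 1 itself stood at 0.48. The same markers lean against an untreated liver under a wrong label but cannot exclude it. Replicate 1 exceeded all controls at 76.9% of them (10 of 13) after median-ratio scaling. A control exceeded the other controls at no more than 53.8%. Genes of a list can vary together within a liver, so such a share can be high in an untreated liver too. Matrix genes left the question open, with 57.1% (8 of 14) for replicate 1 against 71.4% for a control. A different extent of tumour or of injury between the treated livers may be the cause, and the labels hold nothing to test it with.

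Sdha and Sdhb had a mean log2 fold change of -1.19 that did not pass limma's test. After median-ratio scaling it was -0.77 with a standard error of 0.44, so the lower scale of DEN+CCl4 replicate 3 as the whole cause cannot be told apart from a lower level of both genes, because the error spans the bound of -0.5 set for it. The values go with a lower level of nuclear-encoded respiratory chain transcripts as a class, by a rule that only a larger fall of the SDH subunits would have gone against. The median of the 4 SDH subunits (-1.08) differed from that of 66 other nuclear-encoded subunits of complexes I, III, IV and V (-1.16) by 0.0833. Taken per library, the difference between these medians changed from control to DEN+CCl4 liver by 0.0935 with a standard error of 0.136, and by 0.0522 with a standard error of 0.0914 after median-ratio scaling. As deposited, it was -0.04, -0.001 and 0.36 in DEN+CCl4 replicates 1, 2 and 3. The SDH subunits thus fell less than the other subunits in replicate 3. In DEN+CCl4 replicate 3 the list with assembly factors stood at 0.18 from the control mean after median-ratio scaling, beside -1.07 for complex I and -1.20 for complexes III, IV and V. Mitochondrially encoded subunits were not part of this comparison. Those looked up, mt-Co1 and mt-Nd1, had higher means in DEN+CCl4 liver and did not pass. Their log2 fold changes were 0.48 and 0.84 (limma adjusted p = 0.996 and 0.984), and 0.96 and 1.32 after median-ratio scaling. Protein levels were not measured.

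The 10 ways to split the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 71 genes higher and 55 lower, where the highest other split gave 35 in either direction, so that 1 of 10 splits was as large for the genes higher and 1 for the genes lower. It gave 8 lists higher and 10 lower, where the highest other split gave 14, and 7 and 6 of the 10 splits were as large.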
